A study of Homo sapiens with 2 samples.

How the data were processed

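The study sequenced RNA recovered by RNA immunoprecipitation (RIP), in which an antibody against a protein is used to pull down that protein together with the RNA bound to it or lying near it. The cells were MDA-231, a human breast cancer line, treated for 16 h in serum-free medium with the P4G11 antibody against beta-1 integrin. The treatment protocol also lists an antibody E7-s, whose role is not given in the sources used here. The first library came from a RIP with an antibody against MT1-MMP, the membrane-anchored matrix metalloproteinase encoded by MMP14, and the other from a mock RIP with rabbit IgG. The labels are not uniform. The design text names MT1-MMP as the target while the sample title writes MMP1, the name of a different, secreted collagenase, and the cell line tag of the mock sample reads MDA-232. The design text was followed for both libraries.

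The deposited table holds whole-number read counts for 60649 rows, each named by a gene symbol or clone name, in 1 column per library, with totals of 31636000 and 13003668. Each column was tied to its library by the column name given in the labels. Per the submitters' processing notes, cutadapt, HISAT2 and SAMtools were used and the genome build was hg38. Their versions and settings, the counting tool, the annotation and the use of strand are not given in the sources used here. The counts themselves show that overlapping rows can receive the same reads: RPS29 held 36627 IgG counts and RN7SL1, which lies inside its span, held 36579. Reads in introns and in nested or overlapping genes therefore have to be taken as part of a gene's count, and antisense partners cannot be told apart. No row lacked a name, and no column was left unmapped.

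Row names were matched to the RefSeq table of GRCh38.p14, directly for 38374 rows and through an older symbol for the others of the 39002 that matched. Gene class, position and span (start to end, introns included) were taken from it, in the same build as that of the counts. 19238 matched rows were protein-coding. Another 1368 rows had names shared by rows with different counts and were not named, and 539 rows that repeated both the name and the counts of an earlier row were left out of all comparisons but not of the library totals. A block of 28 consecutive rows on chromosome 21, holding the 5.8S ribosomal RNA genes RNA5-8SN1, RNA5-8SN2 and RNA5-8SN3, is called the ribosomal DNA block below. Several of its rows hold nearly equal counts, so the same reads enter its share, and the totals, more than once. The RefSeq precursor genes RNA45SN2 to RNA45SN1 at this place run from 8205988 to 8446572.

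With 1 library per group there is no replicate error, and no p-value was computed. For each of the 25933 rows with at least 20 counts summed over both libraries, the ratio of MT1-MMP RIP to IgG RIP was scaled by trimmed mean of M-values (TMM) factors from edgeR 4.0.16 and given an exact (Clopper-Pearson) 95% interval, conditional on the summed count. These intervals, and the exact binomial intervals of shares, cover counting error only. They leave out variation between immunoprecipitations, and reads without molecular identifiers are not independent molecules. A gene was counted as higher in a library where its whole interval lay beyond 2-fold. Log2 ratios were computed after adding 0.5 counts to each library before scaling. This draws low genes toward a raw ratio of 1, which lies on the IgG side of the scale. A scaled ratio of 1 equals 45.9 MT1-MMP counts to 1 IgG count. Among the 25933 tested rows, 5098 had 0 IgG counts, so their log2 ratios depend on this addition. Where the IgG count was 0, any fold is a lower bound against a floor of 3 counts. An effective IgG depth far below that of the MT1-MMP library limits what can be counted as higher: with 0 IgG counts, at least 341 MT1-MMP counts were needed.

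In all, 29 gene lists were fixed before the data were examined, among them markers of other cell types. For each list the median log2 ratio was set against 10000 random lists of the same size drawn from 20 bins of mean expression (the mean of both log2 levels), and its percentile among them describes these 2 libraries only. A list is said to stand apart below the 2.5th or above the 97.5th percentile. The same was done with 10 bins of expression crossed with 10 bins of gene span. Members of the lists were not left out of the rows drawn from. The interval of a list median is the order-statistic interval over its members. Pseudogene rows matching the name pattern of a family were left out. The genes named were also chosen by a rule fixed beforehand: the 12 protein-coding and 5 noncoding genes whose interval bound lay farthest from 1 in each direction, MMP14, MMP1 and ITGB1, and up to 4 members of each list chosen the same way in the direction of the list's median.

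The alternatives were scaling by total counts (plain CPM), by DESeq2 1.42.0 size factors or by the upper quartile, a minimum of 1 or 100 summed counts, protein-coding genes only, mitochondrial rows left out, the deeper library thinned to the total of the shallower, a lowess trend on gene span removed (statsmodels 0.14.6, span fraction 0.3), and 2 or 5 counts added before the log. Further alternatives, chosen after seeing the data, scaled by totals outside the ribosomal DNA block, left out the ribosomal DNA block or kept only genes whose RefSeq span overlaps no other. Shares of counts outside the block were also recomputed, after seeing the data, with RPS29 or 5 long genes of low ratio left out of the class but not of the total.

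The interval and the list comparison were tested on simulated Poisson counts with a mean per gene pooled over both libraries and the effective depths of these libraries. The scale was taken as known and only counting error was simulated. The simulation therefore does not test the choice of scale, the IgG library's own profile or variation between immunoprecipitations. The interval held the true ratio for 97.3% of 25322 genes, and 11 of 25145 unchanged genes were counted beyond 2-fold. Of genes made 4-fold higher in the MT1-MMP RIP, 34.0% of 50 were recovered, and of those made 8-fold higher, 40.0% of 50. In the other direction 57.1% of 42 and 91.4% of 35 were recovered. Unchanged random lists fell outside the central range in 3.0% of 200 draws.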

Results

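RNA that came down with an antibody against MT1-MMP was compared with RNA from a mock RIP with rabbit IgG, in beta-1 integrin antibody-treated MDA-231 breast cancer cells, with 1 library of each kind. The question the design poses is which RNAs are found with MT1-MMP above the mock background. The rows of the MT1-MMP library summed to 31636000 counts and those of the IgG library to 13003668. Counts above 0 were found for 17843 protein-coding genes in the MT1-MMP library and for 13722 in the IgG library, and 10 or more counts for 15211 and 8093. Neither library has a replicate, so the differences below hold between these 2 libraries and have no replicate check.

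Ribosomal RNA filled most of the IgG library and a small part of the MT1-MMP library. The ribosomal DNA block on chromosome 21 took 92.6% of the IgG counts (95% exact interval 92.58 to 92.61) and 10.2% of the MT1-MMP counts (10.21 to 10.23), some reads being counted in several of its rows. Protein-coding genes held 68.5% of the MT1-MMP counts and 5.24% of the IgG counts, and long noncoding RNA genes 6.92% and 0.180%. Outside the block the totals were 28401567 and 962952 counts, and there protein-coding genes held 76.3% of the MT1-MMP counts and 70.8% of the IgG counts. RPS29, ANKRD30BL, SLCO5A1, PDE3A and HFM1 alone held 27.8% of all IgG counts outside the block and 0.296% of the MT1-MMP counts. With these 5 genes left out of the class but not of the total, protein-coding genes held 76.0% of the MT1-MMP counts and 42.9% of the IgG counts. Genes of the cytosolic ribosomal proteins took 4.68% of the IgG counts outside the block (4.64 to 4.72) and 0.116% of the MT1-MMP counts (0.115 to 0.117). With RPS29, whose IgG counts were nearly equal to those of RN7SL1 inside its span, left out in the same way, these shares were 0.876% (0.858 to 0.895) and 0.0867% (0.0856 to 0.0878). All 37 rows of the mitochondrial genome were listed at 0 in both libraries.

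**Figure D1:**
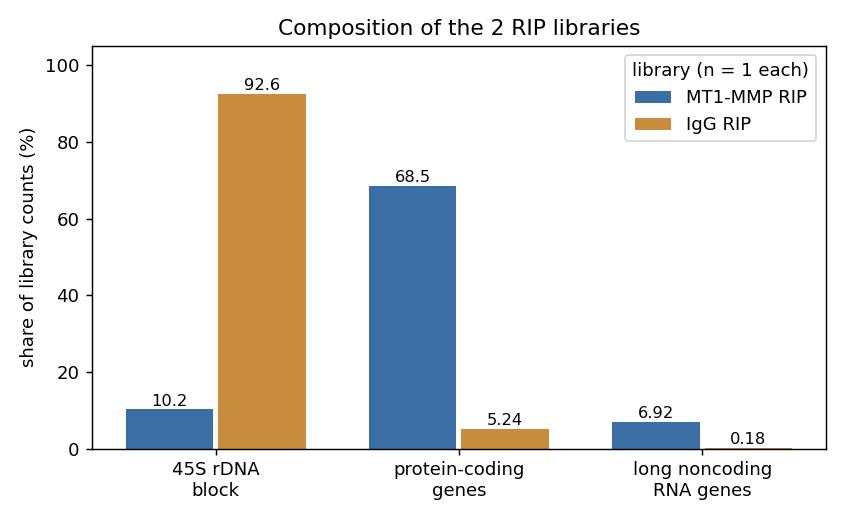
Share of each library's counts (percent, y axis) in the ribosomal DNA block, in protein-coding genes and in long noncoding RNA genes (x axis), for the MT1-MMP RIP and the IgG RIP, 1 library each. The block takes 92.6% of the IgG library and 10.2% of the MT1-MMP library, while protein-coding genes take 5.24% and 68.5%.

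Because the block fills most of the IgG library, the choice of scale sets the level of every other gene. By total counts the median tested row was 21.2-fold higher in the MT1-MMP library. Under TMM scaling, which sets the typical row near 1, a raw ratio of 45.9 counts to 1 equals a scaled ratio of 1, and total counts lie 4.24 above it on the log2 scale. All ratios, and the words higher and lower, are below relative to the typical row under TMM, unless plain CPM is named. By plain CPM each gene lies 4.24 higher, so many ratios below 0 turn positive. By totals without the block, a scale chosen after seeing the data, each gene lies 0.64 higher.

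The mRNA of the RIP target, MMP14 (GRCh38 chromosome 14, 22836585 to 22847758), had 367 counts in the MT1-MMP library and 134 in the IgG library. In plain CPM these are 11.6 and 10.3, a log2 ratio of 0.17 whose 95% interval, -0.12 to 0.47, includes 0. Relative to the typical row the log2 ratio was -4.07 (95% interval -4.36 to -3.77), which places MMP14 mRNA lower in the MT1-MMP library, and by totals outside the block it was -3.43. MMP1, named in the sample title and located on chromosome 11 at 102789919 to 102798160, had 583 and 361 counts, a scaled log2 ratio of -4.83 (-5.02 to -4.64) and a plain CPM log2 ratio of -0.59. The overlapping row WTAPP1 held nearly the same counts as MMP1. ITGB1, which encodes beta-1 integrin, the antigen of the treatment antibody, had 8940 and 269 counts. Its scaled log2 ratio of -0.47 (-0.64 to -0.29) stayed within 2-fold of the typical row, and it was 3.77 by plain CPM and 0.17 by totals outside the block.

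Across the 14318 protein-coding genes tested, 1037 (7.24%) were more than 2-fold higher in the MT1-MMP library beyond counting error, 2321 (16.2%) were more than 2-fold higher in the IgG library, and 10960 were neither. Over all 25933 rows the numbers were 1529 and 3323, with total counts as the scale they became 22244 and 234, and with totals outside the block 3733 and 2380. The protein-coding genes higher in the MT1-MMP library had a median span of 210.1 kb, against 10.0 kb for those higher in the IgG library and 42.1 kb for the remainder. Depth enters these spans, since a call as higher at 0 IgG counts needed 341 MT1-MMP counts. The tenth of genes with the shortest spans had a median of 54.

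The 12 protein-coding genes that led in the MT1-MMP library by the lower bound of their interval had spans from 42.7 kb for ZER1 to 1113 kb for WWOX. EXT1 (chromosome 8, 117794490 to 118111826), a glycosyltransferase that builds heparan sulfate, had the most counts of the 12, 238350 against 1042 (log2 ratio 2.32, 95% interval 2.23 to 2.41). Others without a large overlapping row were NLGN1, a synaptic adhesion protein (2.69, 2.29 to 3.17), LDLRAD3, a low-density lipoprotein receptor family member (2.74, 2.26 to 3.32), and ZER1, a substrate receptor of a ubiquitin ligase (2.95, 2.25 to 3.87). So were ERP44, a chaperone of the early secretory pathway (2.79, 2.25 to 3.46), ACYP2, an acylphosphatase (2.69, 2.24 to 3.22), and EFNA5, the ligand ephrin-A5 (2.42, 2.21 to 2.64), as well as WWOX, an oxidoreductase gene at a common fragile site (2.48, 2.16 to 2.84), and KCNQ5, a potassium channel (2.37, 2.16 to 2.60). EYA4 and COL10A1 rested on 2 and 1 IgG counts, with log2 ratios of 3.83 (2.30 to 7.20) and 4.19 (2.30 to 10.08). COL10A1, EYA4 and FILIP1L (5.70-fold, 4.52 to 7.31) overlap NT5DC1, TARID and CMSS1, whose rows hold comparable or larger counts, so their ratios cannot be assigned to them alone.

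The 12 protein-coding genes that led in the IgG library by the upper bound were of 2 kinds. The short genes were the replication-dependent histones H3C2 (log2 ratio -7.99, 95% interval -9.26 to -7.02) and H4C11 (-7.34, -8.21 to -6.60), the cystatin CST1 (-8.21, -10.04 to -6.97), the small GTPase RAB13 (-7.18, -7.63 to -6.77), the centromere protein CENPB (-7.45, -8.32 to -6.72), the calcium-binding protein S100A6 (-6.93, -7.19 to -6.67) and the cytokine MIF (-7.54, -8.68 to -6.61). S100A6, for example, had 174 MT1-MMP counts and 462 IgG counts, and MIF shares its reads with MIF-AS1. The other 5 had spans from 27.7 kb to 320.0 kb: ANKRD30BL (-8.72, -8.80 to -8.65), RPS29 (-7.66, -7.70 to -7.63), SLCO5A1 (-7.52, -7.56 to -7.49), PDE3A (-7.27, -7.29 to -7.25) and HFM1 (-6.84, -6.86 to -6.83). RPS29 shares its counts with RN7SL1, an RNA of the signal recognition particle, whose row equalled 99.9% of its IgG counts. All 12 were also higher in the IgG library by plain CPM.

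Among noncoding genes, the 5 with the lowest upper interval bound were rows of the ribosomal DNA block and of the signal recognition particle RNA: MIR6724-4 (log2 ratio -8.31), RNA5-8SN1 (-7.99), RNA5-8SN3 (-7.98), MIR6724-2 (-7.92) and RN7SL2 (-7.82), each with a 95% interval under 0.1 wide. The 5 with the highest lower bound were ST7-OT4 (3.02, 2.34 to 3.90), COX10-AS1 (3.03, 2.28 to 4.04), FAM155A-IT1 (2.70, 2.20 to 3.30), LINC00907 (3.13, 2.19 to 4.55) and FAM27C (2.53, 2.16 to 2.95). ST7-OT4 and FAM155A-IT1 overlap the larger genes ST7 and FAM155A.

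The ratio followed gene span through its whole range. In the tenth of protein-coding genes with the shortest spans (up to 6.68 kb) the median log2 ratio was -2.73 (interquartile range -4.35 to -1.06), with 795 of 1432 genes higher in the IgG library and 5 higher in the MT1-MMP library. In the tenth with the longest spans (194.1 kb and above) it was 1.47 (0.90 to 1.94), with 559 of 1432 genes higher in the MT1-MMP library and 20 in the IgG library. The median rose at every step between them. Across genes, which are not independent replicates, Spearman's rho between span and ratio was 0.62 (Pearson's r on log2 span 0.62), and it was 0.59 over the 5365 genes whose span overlaps no other. MT1-MMP counts followed span with a rho of 0.57 and IgG counts with a rho of 0.16. These 2 values are not directly comparable, since counting noise lowers the IgG value more. The median tested protein-coding gene had 388 MT1-MMP counts and 12 IgG counts, and 1307 such genes had 0 IgG counts.

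**Figure D2:**
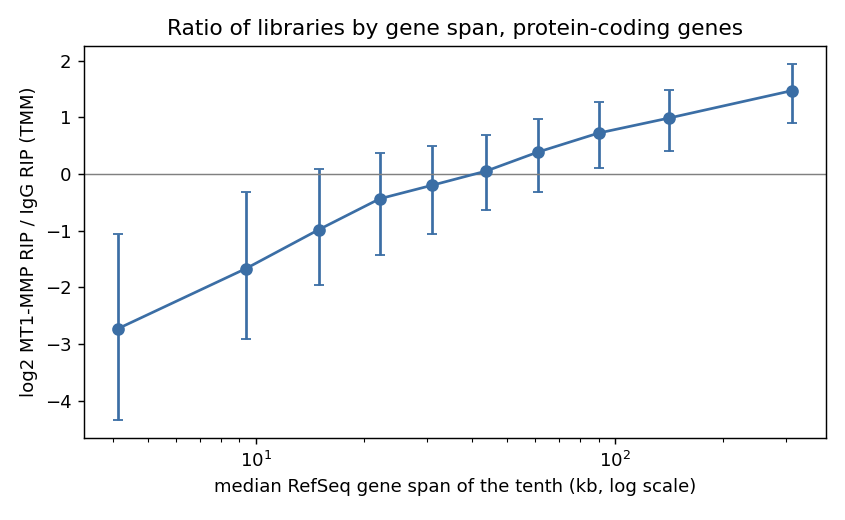
Median log2 ratio of MT1-MMP RIP to IgG RIP (TMM-scaled, y axis) in 10 equal groups of protein-coding genes ordered by RefSeq span (kb, log x axis); points are medians over genes, bars the interquartile range, from 1 library of each kind. The median climbs from -2.73 in the shortest group to 1.47 in the longest.

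Genes for the translation machinery were lower in the MT1-MMP library as a group. Of 80 measured cytosolic ribosomal protein genes, 74 were more than 2-fold higher in the IgG library and 0 in the MT1-MMP library, with a median log2 ratio of -4.60 (95% interval -4.87 to -4.16) against 0.27 in expression-matched random lists. RPL8 (-6.92), RPS21 (-7.11) and RPS27 (-6.56) were examples. Of 36 translation factors, 25 were higher in the IgG library and 0 in the MT1-MMP library (median -2.19), led by the elongation factors EEF2 (-5.93), EEF1B2 (-5.71) and EEF1A1 (-5.24). Mitochondrial ribosomal proteins (22 of 70 higher in the IgG library, 1 in the MT1-MMP library, median -1.42) and nuclear-encoded respiratory chain subunits (45 of 72 and 1, median -2.24), such as COX7C (-5.82) and ATP5ME (-6.26), lay on the same side. By plain CPM these 4 medians were -0.37, 2.05, 2.81 and 1.997. All 4 lists stood apart below the expression-matched lists, each at percentile 0. With gene span matched as well, the ribosomal proteins (2.10 below the matched lists, percentile 0), translation factors (1.37 below, percentile 0.02) and respiratory chain subunits (0.85 below, percentile 0.16) still did, and the mitochondrial ribosomal proteins did not (0.39 below, percentile 8).

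Several other gene groups also lay below the typical row. Replication-dependent histones had the lowest median of all lists, -6.32 (-6.50 to -5.61), with 34 of 35 members higher in the IgG library, among them H4C12 (-7.27) and H1-4 (-6.50). Chaperones of the heat shock response had a median of -3.12, with 18 of 23 higher in the IgG library, including HSPA8 (-5.90) and HSPB1 (-7.02, on 5 and 15 counts). Glycolytic enzymes had a median of -2.02, with 11 of 19 higher in the IgG library; GAPDH had 286 MT1-MMP counts and 661 IgG counts (-6.73, -6.93 to -6.53), and TPI1, which overlaps SPSB2, was at -6.90. Cell cycle genes had a median of -1.76 with 18 of 34 higher in the IgG library, including MCM7 (-4.33) and CCND1 (-3.91). Genes of protein entry into the endoplasmic reticulum had a median of -1.25 with 16 of 37, including CALR (-4.13) and SSR4 (-4.90), which overlaps IDH3G. None of these 5 lists had a member counted as higher in the MT1-MMP library, and each stood apart below the matched lists with and without matching on span (percentiles 0 to 0.31), but the endoplasmic reticulum list did not over its 16 genes without overlap (28.8, shift -0.18 against -1.50). By plain CPM, the medians of the ribosomal protein list (-0.37) and the histone list (-2.08) were the only ones below 0 among the 28 measured lists, and those of the chaperone, glycolysis, cell cycle and endoplasmic reticulum lists were 1.11, 2.21, 2.48 and 2.99.

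Among the lists closest to MT1-MMP and beta-1 integrin, no list lay above its matched lists. Of 20 measured matrix metalloproteinases and regulators, 7 were higher in the IgG library and 0 in the MT1-MMP library (median -0.49, 95% interval -3.68 to 0.56). The list stood at percentile 6.12, but apart below its matched lists with a minimum of 1 count (0.05), with 2 or 5 counts added (0.63 and 0.12) and over its 6 genes without overlap (1.09). Counts added before scaling draw low genes toward the IgG side, in the list and its matched lists. The minimum of 1 count also let in members of lower counts, 33 in all. These 3 settings are therefore not independent evidence of a low list. The 7 members higher in the IgG library included the metalloproteinase inducer BSG (-4.38) and TIMP1 (-6.62, on 10 and 22 counts and overlapping SYN1). Integrin subunits had 3 of 21 higher in the IgG library and 0 in the MT1-MMP library (median -0.03), namely ITGB4 (-3.52), ITGA5 (-2.85) and ITGA3 (-2.18), whose plain CPM log2 ratios were 0.71 (0.24 to 1.24), 1.39 (0.96 to 1.87) and 2.06 (1.86 to 2.27), and the list stood at percentile 18.9, or 2.08 with span matched. Focal adhesion and invadopodia components (2 higher in the MT1-MMP library, 8 in the IgG library, 25 neither, median -0.35, percentile 0.09) included FLNA (-4.97) and CFL1 (-4.99). Collagens, laminins and other matrix proteins (2 and 14 of 36, median -0.59, percentile 0.41) included COL6A1 (-5.52) and LAMB2 (-4.58). Surface and secreted MT1-MMP substrates (1 and 10 of 23, median -1.35, percentile 0) included the lectin LGALS1 (-6.06) and the matricellular protein CCN1 (-4.99). YAP and TAZ targets (5 and 9 of 26, median -0.37, percentile 0.62) included CCN2 (-5.56). Over genes without overlap the matrix list (9 genes, percentile 4.33) and the substrate list (5 genes, 5.47) did not stand apart, with fewer genes and shifts from the matched lists of -1.47 and -1.52, against -0.97 and -1.64 over all members. Neither did the YAP and TAZ list with 5 counts added (2.72).

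In the TGF-beta and SMAD list 7 of 25 genes were higher in the MT1-MMP library and 3 in the IgG library, with a median of 0.92 (0.72 to 1.25) at percentile 90.8, which does not stand apart. It did with the span trend removed (percentile 99.5), but not with span matched (88.7). Members named by the rule were SMAD3, a transcription factor downstream of the TGF-beta receptors (55779 against 326 counts, 1.90, 1.74 to 2.06), the ligand TGFB2 (3.74-fold, 2.83 to 5.04) and the receptors BMPR1A (1.81, 1.27 to 2.46) and ACVR2A (2.56, 1.48 to 4.33, on 5 IgG counts), whose reads cannot be told from those of the overlapping ORC4. NOTCH signalling genes were split, 4 of 19 each way (median 0.15, percentile 34.3), with the co-activators MAML2 (2.22, 2.06 to 2.40) and MAML3 (2.40, 1.97 to 2.90) among the higher, although MGST2, which overlaps MAML3, held nearly as many IgG counts. Genes of epithelial to mesenchymal transition and metastasis had 3 of 24 higher in the MT1-MMP library, TNC (2.22), TGFB2 and the receptor EGFR (1.41), and 9 higher in the IgG library. Their median of 0.08 became -0.28 with a gene at 0 IgG counts set to its floor. The N6-methyladenosine writers, erasers and readers had 2 of 26 higher in the MT1-MMP library and 6 in the IgG library (median -0.18, percentile 6.06), the latter including PRRC2A (-4.58) and HNRNPA2B1 (-2.18, but 2.05 by plain CPM). In the main comparison, zinc finger transcription factors were the single list that stood apart above its matched lists when these were matched on expression alone: 26 of 433 were higher in the MT1-MMP library and 17 in the IgG library, with a median of 0.42 (0.29 to 0.53) at percentile 100. Both shares lay below those over all tested protein-coding genes, 7.24% and 16.2%. Far above the list median were ZNF678 (3.05, 2.16 to 4.35, on 8 IgG counts) and ZNF407 (2.27, 1.88 to 2.72).

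Nuclear long noncoding RNAs had 6 of 19 higher in the MT1-MMP library, including PVT1 (2.11, 1.94 to 2.29), MIR100HG (1.95), FTX (1.95) and LINC-PINT (2.09, shared with LINC00513), and 4 higher in the IgG library, with a median of 0.925 at percentile 88.2. Small structured RNAs transcribed by RNA polymerase III had 8 of 9 higher in the IgG library (median -4.16, percentile 0, but 14.3 with span matched), among them RN7SL2 (-7.82), RN7SL1 (-7.79), RN7SL3 (-7.11) and RPPH1 (-3.50). Small nucleolar RNAs had 61 of 98 higher in the IgG library and 0 in the MT1-MMP library (median -3.84, percentile 0), although rows such as SNORD72 and SNORD82 lie inside host genes. Spliceosomal small nuclear RNAs lay closer to the typical row (1 of 12 higher in the IgG library, RNU4-2 at -2.28, median -0.78, percentile 3.01), and with span matched they lay 1.59 above the matched lists (percentile 87.9). Lists matched on so short a span draw on other short RNAs, among them small nucleolar RNAs, which lay low themselves. The span-matched percentiles of the polymerase III and spliceosomal lists therefore do not separate span from RNA class. By plain CPM the medians of the polymerase III, nucleolar and spliceosomal lists were 0.08, 0.40 and 3.46.

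**Figure D3:**
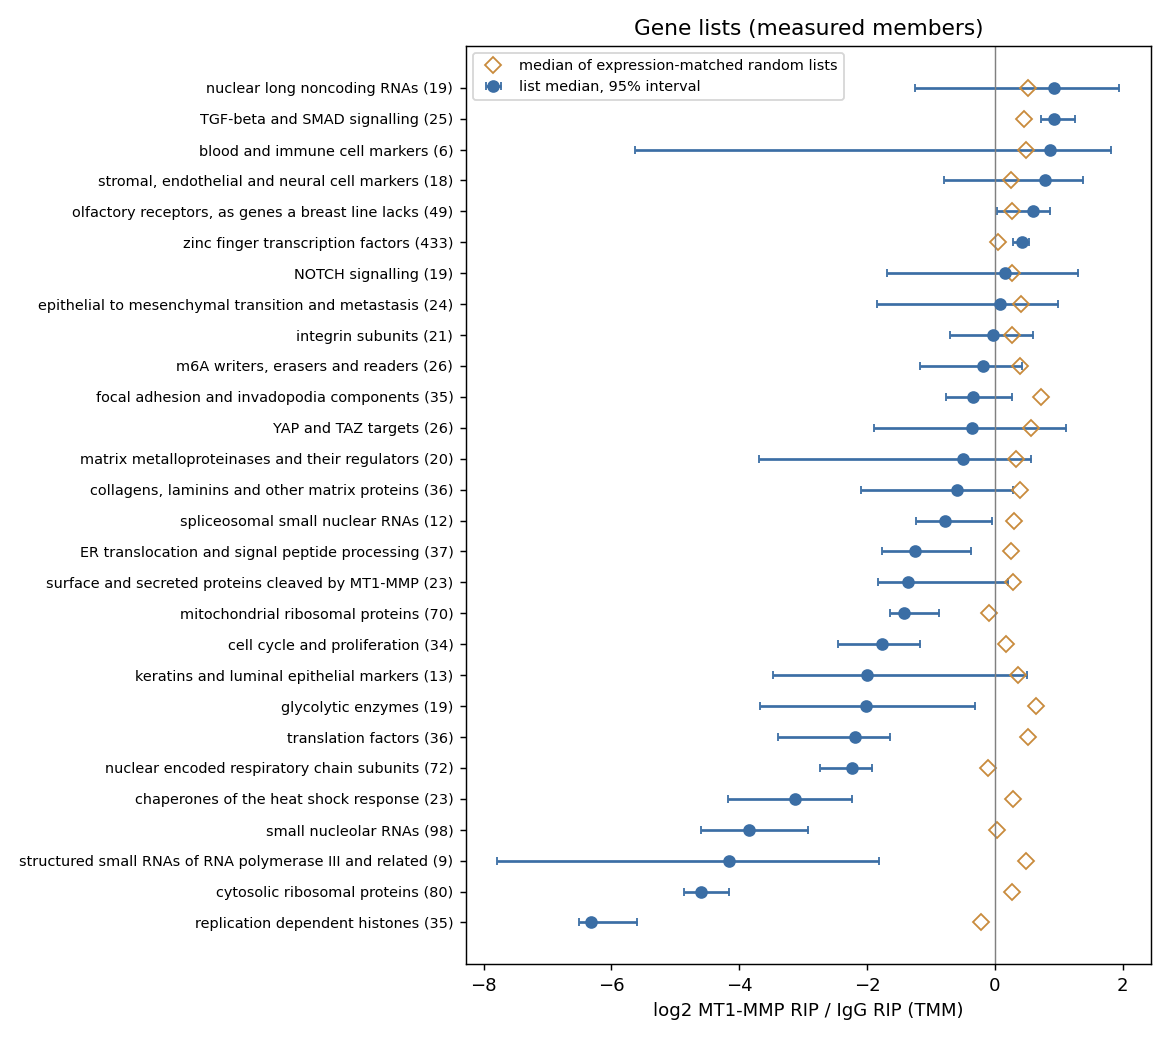
Median log2 ratio of MT1-MMP RIP to IgG RIP (TMM-scaled, x axis) of 28 measured gene lists (y axis, number of measured members in brackets), with the 95% order-statistic interval over members as bars and the median of expression-matched random lists as open diamonds, from 1 library of each kind. Replication-dependent histones at -6.32 and cytosolic ribosomal proteins at -4.60 lie farthest below their matched lists, and by plain CPM they are the 2 lists with medians below 0, at -2.08 and -0.37.

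Among markers of cell types, the keratin list alone stood apart, and by plain CPM its median was 2.23. Keratins and luminal epithelial markers had 6 of 13 measured members higher in the IgG library and 0 in the MT1-MMP library (median -2.01, percentile 0.02), including KRT19 (-5.56) and KRT18 (-6.04, overlapping KRT8). Only 6 of 24 blood and immune markers reached 20 counts, with 464 MT1-MMP counts in all over the list. Of these 6, 2 were higher in the IgG library and 0 in the MT1-MMP library, where those at 0 IgG counts held too few counts to be called. Their median of 0.86 (-5.63 to 1.81) became -1.27 with genes at 0 IgG counts set to their floor. Of 18 stromal, endothelial and neural markers, 3 were higher in the MT1-MMP library, SYT1 (2.41), MBP (1.37) and PECAM1 (1.60), and 1 in the IgG library (median 0.79, percentile 94.8, median 0.10 at the floor). With span matched this list lay 0.14 below the matched lists, at percentile 34.0. Olfactory receptors, taken as genes this line should not use, reached 20 counts in 49 of 387 cases with 0 higher in the MT1-MMP library, 1 higher in the IgG library and 24 at 0 IgG counts, and their median of 0.59 (percentile 95.7, or 99.7 with span matched) became -1.22 at the floor. The named member with the highest lower bound, OR1L6, had 297 MT1-MMP counts and 0 IgG counts. That is under the 341 needed for a call as higher, so depth kept the genes at 0 IgG counts from being called. Setting genes at 0 IgG counts to their floor moved the medians of other lists to -0.21 for integrins, -1.08 for collagens and matrix proteins, -1.43 for MT1-MMP substrates, 0.01 for NOTCH genes, -1.37 for endoplasmic reticulum entry, -1.85 for cell cycle genes, 0.28 for zinc finger genes and -2.11 for keratins.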

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

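No paired analysis was possible because each group holds 1 library, and for the same reason no replicate could be left out. Scaling changed the gene counts and single ratios. It cannot test the lists, since it adds 1 constant to every gene and to the matched lists alike. By total counts, 22244 rows were higher in the MT1-MMP library and 234 in the IgG library, against 1529 and 3323 with TMM, and the MMP14 log2 ratio turned from -4.07 to 0.17. On that scale these log2 ratios also changed sign: ITGB1 3.77, HNRNPA2B1 2.05, ITGB4 0.71, ITGA5 1.39, ITGA3 2.06, CALR 0.10, CCND1 0.33, RPPH1 0.74, RNU4-2 1.96 and KRT8 1.34. The scale alone does this, since it adds 4.24 to every gene. Totals outside the ribosomal DNA block, added after seeing the data, gave 3733 and 2380 rows, MMP14 at -3.43 and ITGB1 at 0.17, the latter also changed in sign. DESeq2 size factors (1388 and 3392) and the upper quartile (1923 and 3079) changed the counts less. A minimum of 1 count gave 2712 rows higher in the MT1-MMP library and a minimum of 100 counts 625, with MMP14 at -3.71 and -4.49. With the span trend removed, the number higher in the MT1-MMP library was 396 of 18847 rows, and MMP14 was at -3.21. Keeping the 6603 genes without overlap, an alternative chosen after seeing the data, gave 477 and 982, with fewer genes tested, and MMP14 at -3.58. The number of lists standing apart, 17 of 28, stayed between 15 and 20 under every alternative run, each with 24 to 28 lists, but not always for the same lists. With span matched, the polymerase III and mitochondrial ribosomal lists no longer stood apart (percentiles 14.3 and 8) and the integrins (2.08) and olfactory receptors (99.7) did. For the polymerase III list, the matched lists draw on other short RNAs that lay low themselves. With the span trend removed, the mitochondrial ribosomal list was lost (28.8), and the transition and metastasis (1.79), TGF-beta (99.5), nuclear long noncoding (98.2) and olfactory (99.6) lists were gained. Genes without overlap lost the matrix (4.33), MT1-MMP substrate (5.47), endoplasmic reticulum (28.8) and mitochondrial ribosomal (4.05) lists, on 9, 5, 16 and 42 genes. Their shifts from the matched lists were -1.47, -1.52, -0.18 and -0.72, against -0.97, -1.64, -1.50 and -1.32 over all members. The same setting gained the metalloproteinases (1.09) and olfactory receptors (98.3). The metalloproteinases were also gained with a minimum of 1 count (0.05) and with 2 or 5 counts added (0.63 and 0.12). With 5 counts added the YAP and TAZ list was lost (2.72) and the transition list gained (2.41). Added counts draw low genes toward the IgG side, so changes under these settings are not independent evidence about a list. A minimum of 100 counts gained the small nuclear RNAs (0.17) and the stromal list (98.6), thinning gained the small nuclear RNAs (0.72), and protein-coding genes alone gained the olfactory receptors (98.6). Leaving genes that may hold other rows' reads out of their class but not of the total, also chosen after seeing the data, moved shares outside the block. Without RPS29 the ribosomal protein share was 0.876% of IgG and 0.0867% of MT1-MMP counts. Without RPS29, ANKRD30BL, SLCO5A1, PDE3A and HFM1 the protein-coding share was 42.9% and 76.0%. Leaving out the mitochondrial rows changed nothing because all were at 0, and no row lacked a gene name. The cause of the other differences was not tested. Depth limits the IgG side: the median tested protein-coding gene had 12 IgG counts and 388 MT1-MMP counts.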

Other observations

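The tests below were chosen after the ratios had been seen, except those on IgG depth and on intronless genes. The genes in this paragraph were also chosen after their values were seen. ACTB was at a log2 ratio of -3.45 (95% interval -3.57 to -3.34) and VIM at -4.19 (-4.32 to -4.06), neither of them lower by plain CPM. Long noncoding RNAs did not behave as 1 group: CYTOR (2.04, 1.91 to 2.17), which has a near-identical copy with which its reads are not told apart with certainty, was higher in the MT1-MMP library, MALAT1 was at 0.85 (0.79 to 0.92) and NEAT1 at -0.08 (-0.17 to 0.02). Among the N6-methyladenosine genes, the reader IGF2BP2 was higher in the MT1-MMP library (25649 against 154 counts, 1.85, 1.63 to 2.10) and the writer METTL3 was at -0.56 (-1.23 to 0.30).

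The rise of the ratio with gene span is the pattern most worth following up, because long genes lead the comparison. Genomic DNA in the MT1-MMP library would cover silent genes as densely as transcribed ones, but 387 olfactory receptor genes had a median of 0 counts per kb, 0% of the 13.7 counts per kb of tested protein-coding genes, which argues against DNA as the whole cause. The shallow IgG library does not account for it either, since rho was 0.69 over 8500 genes after the MT1-MMP counts outside the ribosomal DNA block were thinned to the IgG total there. A candidate explanation is more unspliced RNA in the MT1-MMP library, but 29 intronless genes, with a median of -2.25 against -1.78 in lists matched on span and expression, stood at percentile 22.1, which does not decide it. Whether the antibody binds a different RNA population, or 1 preparation held more nuclear RNA, cannot be told apart with 1 library per group.

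The 5 longer genes among the lowest ratios may owe their place to sequence inside their spans. For RPS29, the RN7SL1 row inside its span held 99.9% of its IgG counts and 91.5% of its MT1-MMP counts, as reads counted for both rows would give. For ANKRD30BL, SLCO5A1, PDE3A and HFM1, ribosomal RNA-like sequence is a hypothesis: 2 of the 4 had log2 ratios inside the range of the 22 larger block rows, -8.305 to -7.245, which leaves it open without a genome sequence to search.

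The mitochondrial rows at 0 are consistent with reads of the mitochondrial genome having been left out before or during counting. All 37 rows were at 0 in both libraries, while 11 nuclear pseudogene copies held 20 or more counts in both, among them MTCO1P12 (283 MT1-MMP counts, 1271 IgG counts) and MTATP6P1 (72 and 517). No biological explanation was tested for this pattern.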
